A study of Arabidopsis thaliana with 21 samples.

How the data were processed

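RNA of 14-day-old Arabidopsis thaliana seedlings was sequenced from 7 groups of 3 libraries: the wild types Col-0 and Ler, asil1-1 and asil2-1 in Col-0, asil2-2 in Ler, asil1-1 asil2-1 in Col-0, and asil1-1 asil2-2, whose labels name both ecotypes. The replicates are called biological in the series design text. Per the labels, seedlings grew at 22 °C in 16 h of light on sucrose-free MS plates, and polyA libraries were made from 5 ug of total RNA. The deposited files hold raw counts of reads, in the unit count, for 1 transcript model per locus, without a header line, and list only loci with at least 1 count. Per the submitters' processing notes, Bowtie 0.12.7, edgeR 3.0.8 and the TAIR10 genome were used. Strand, the treatment of multiply mapping reads and the counting program are not given in the sources used here.

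The 21 files hold 24100 loci, of which 23867 were found in the TAIR10.1 gene table and 160 are organellar. Depth per library, in M counts (1e6) for replicates 1, 2 and 3, was 8.41, 10.29 and 10.12 in Col-0, 6.52, 28.79 and 14.13 in Ler, 13.58, 11.02 and 8.03 in asil1-1, 11.06, 18.28 and 12.56 in asil2-1, 13.41, 23.43 and 20.94 in asil2-2, 11.53, 15.32 and 13.51 in asil1-1 asil2-1, and 13.82, 14.63 and 12.76 in asil1-1 asil2-2. Between 20305 and 21901 loci were detected per library, and 3 counts correspond to 0.104 CPM in the deepest library and 0.46 CPM in the shallowest. No library was left out.

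Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr (19589 tested, 4511 removed), scaled by TMM, and fitted with 1 mean per group over all 21 libraries (14 residual degrees of freedom) by the robust quasi-likelihood method. Adjusted p values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05, and errors of fold changes are derived from the quasi-likelihood F statistic. Comparisons were each mutant against the wild type of its background, asil1-1 asil2-2 against both wild types, Ler against Col-0, asil1-1 asil2-1 against asil1-1 and asil2-1, the non-additivity of asil1-1 and asil2-1, and the difference of the asil2-2 and asil2-1 effects. Genes changed against both wild types passed the threshold in the same direction in both comparisons, with the smaller fold change and the larger adjusted p reported.

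In total 22 gene lists of 354 members were fixed before the data were examined. Of these members 5 were dropped because the gene table assigns the symbol to another locus, 337 of the other 349 were listed in the files and 278 were tested. Lists with at least 3 members tested went to camera (limma 3.58.1) with a preset correlation of 0.01, 180 tests in 9 comparisons with Benjamini-Hochberg adjustment. An estimated correlation and fry were the alternatives. A second adjustment over the members of a list alone is given beside counts of members.

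Genes named in the text follow a rule that was also fixed before the data were examined: ASIL1 and ASIL2 in every group; in each comparison, among called genes whose libraries do not overlap between the groups, the 6 with the largest fold change and the 6 with the smallest p in each direction, leaving out genes without a symbol; and up to 4 members of each list by smallest p. Genes with 1 to 3 counts in a group were left out. Where a group has no count, the fold is a lower bound with 3 counts in total put in that group. ESP and ESM1 are also members of the glucosinolate list. Genes shared by 3 comparisons were named only when the rule named them in 1 of the comparisons.

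Exonic length came from the TAIR10.1 annotation. The length correction subtracts a lowess trend (span 0.3) of each library's log CPM on log length as an offset, and the root score is the mean log2 level of the 18 root markers per library, centred per gene. Both were added after the data were examined, as was a fit with Col-0 replicate 3 as the only Col-0 library. Alternatives fixed beforehand were RLE scaling, a CPM filter of at least 1 in 3 libraries, no filter, DESeq2 1.42.0, organellar genes removed, a fit of the compared groups alone, a replicate block and leaving out each library in turn. Where groups were compared directly, median log2 fold changes under TMM stayed between -0.014 and 0.032, and under library size alone they reached 0.16. Under TMM the median was -0.032 for the non-additivity and -0.018 for the difference of the asil2-2 and asil2-1 effects.

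On the chromosomes, the index of a gene is its log2 level in asil1-1 asil2-2 between the Col-0 mean (0) and the Ler mean (1), for genes called between the wild types with an absolute log2 fold change of at least 1. Overlaps between comparisons were tested by Fisher's exact test against 19589 genes. Sets shared by 3 comparisons were set against the product of the 3 proportions.

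The pipeline was tested on data simulated from the mean levels, spread and depths of all 21 libraries. Changes were added in the asil1-1 libraries alone, to genes with a mean level over 1 CPM, and tested in asil1-1 against Col-0. Recovery of weaker genes was not measured. The pipeline recovered 38.8% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 89.4% of those changed 4-fold, with 4 false calls among 143. With an added length trend 687 of 832 calls were false without the length correction and 6 of 143 with it. The added trend was the same in each asil1-1 library, so a trend that varies within a group was not simulated. A raised list was called by camera, as was 1 of 20 random lists.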

Results

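The seedlings differed in 2 genes that encode trihelix transcription factors, ASIL1 (AT1G54060, chromosome 1) and ASIL2 (AT3G14180, chromosome 3). ASIL1 transcript fell in every line labelled asil1-1: from 33.6 ± 1.25 CPM (counts scaled for library size, mean ± SD, n = 3) in Col-0 to 4.83 ± 0.314 in asil1-1 (6.94-fold lower, adjusted p = 8.21e-11) and 8.01 ± 0.639 in asil1-1 asil2-1 (4.2-fold lower, adjusted p = 8.59e-10). It also fell to 5.66 ± 1.13 in asil1-1 asil2-2 (5.93-fold lower than Col-0, adjusted p = 1.13e-11, and 5.86-fold lower than Ler, adjusted p = 4.75e-12). It was 33 ± 3.32 in Ler, 40.4 ± 5.32 in asil2-1 and 37.9 ± 3.91 in asil2-2, with no change called in either asil2 line. ASIL2 transcript did not fall in any line labelled asil2. It rose from 38.1 ± 8.97 in Col-0 to 435 ± 54.5 in the libraries labelled asil2-1 (11.4-fold higher, adjusted p = 1.33e-09) and 168 ± 32.5 in asil1-1 asil2-1 (4.41-fold higher, adjusted p = 2.86e-07). In asil1-1 asil2-2 it was 75.9 ± 15.5 (1.99-fold higher than Col-0, adjusted p = 0.000687, and 2.38-fold higher than Ler, adjusted p = 7.87e-05). In the libraries labelled asil2-2 it was 24.4 ± 6.45 against 31.6 ± 4.15 in Ler (log2 fold change -0.38 ± 0.20, adjusted p = 0.268), and in asil1-1 it was 54.1 ± 3.57 (0.51 ± 0.20 against Col-0, adjusted p = 0.0834). Whole-gene counts do not say whether such a transcript is complete, so the ASIL2 counts do not check the asil2 labels, and the groups are named as labelled.

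**Figure D1:**
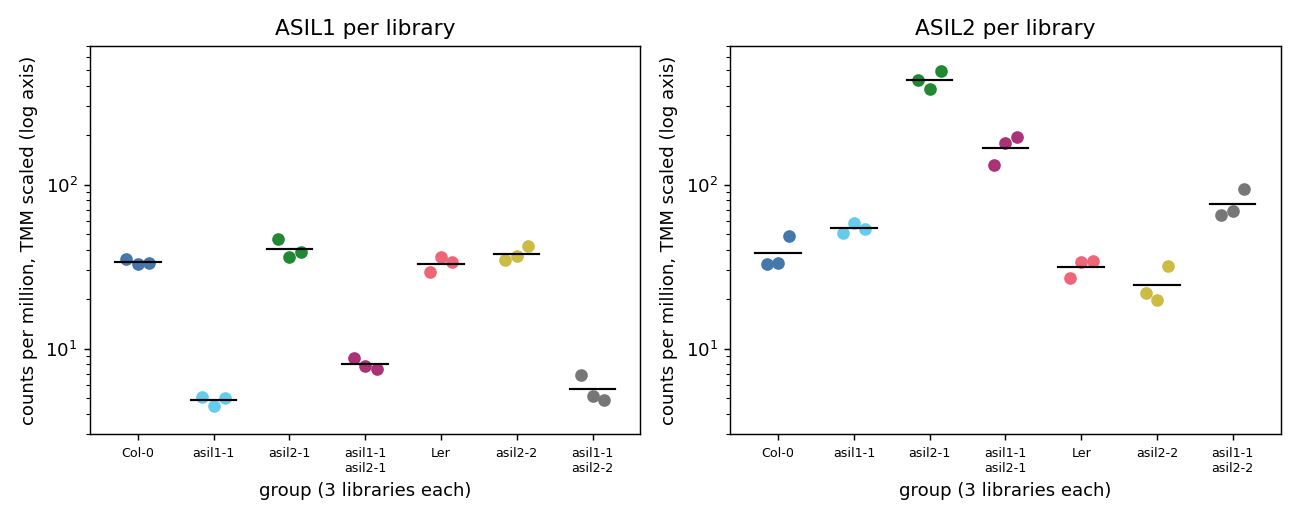
ASIL1 and ASIL2 transcript levels in CPM in each library of the 7 groups, on a log scale.

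Fold changes below are log2 values ± SE from the same model, with n = 3 libraries per group. The counts of genes called in each comparison are over 19589 genes tested. Beside a count of list members, the count adjusted over the list alone is given where it differs. Besides genotype, 2 features of the libraries moved with the groups. Root markers were high in Col-0 replicates 1 and 2 (mean log2 score 1.42 and 1.44) and lower in Col-0 replicate 3 (0.01) and in the asil1-1 libraries (-0.62, -0.98 and -0.85), and they varied in asil2-1 (-1.13, 0.29 and 0.02) and asil1-1 asil2-1 (0.59, -1.22 and -0.75). Long transcripts were relatively higher, and short ones lower, in the mutants and in Ler than in Col-0. The rank correlation of fold change with exonic length across 19485 genes was 0.26 in asil1-1, 0.50 in asil2-1, 0.46 in asil1-1 asil2-1, 0.37 in asil1-1 asil2-2 and 0.29 in Ler, each against Col-0, and 0.25 in asil2-2 against Ler. In asil2-1 the median log2 fold change was -0.88 for transcripts of at most 800 nt and 0.59 for those over 4000 nt. The difference between these length classes also varied within groups, being 0.27, -0.52 and 0.5 in replicates 1, 2 and 3 of asil1-1 asil2-2, 0.26, -0.43 and 0.03 in Ler and 0.25, 0.52 and 0 in asil2-2.

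**Figure D2:**
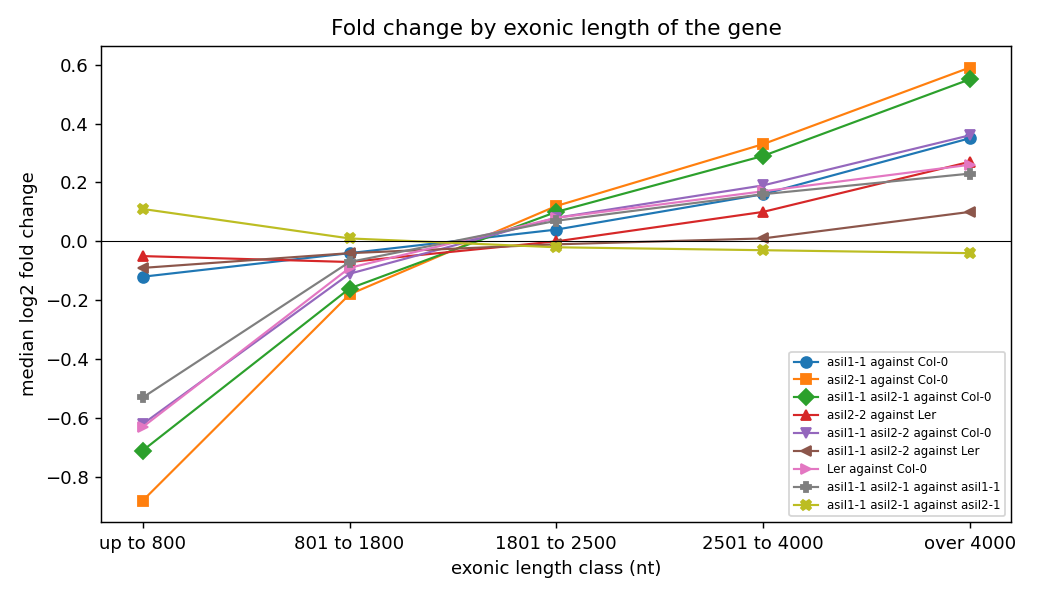
Median log2 fold change of genes by class of exonic transcript length in each comparison.

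**Figure D3:**
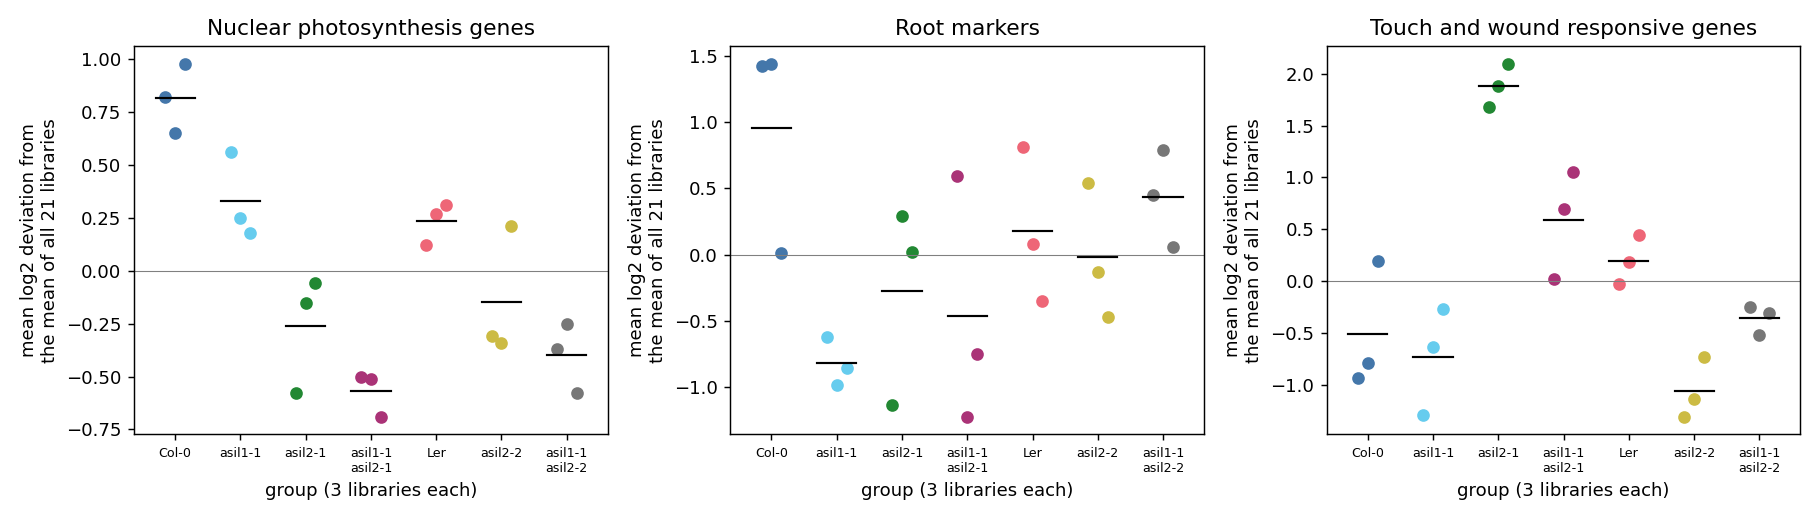
Mean log2 scores of the nuclear photosynthesis genes, the root markers and 11 rapid stress genes in each library.

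In asil1-1 against Col-0, 10 of 13 flavonoid and anthocyanin genes, 12 of 18 root markers, 10 of 15 glucosinolate genes and 12 of 28 nuclear photosynthesis genes fell, in lists that were not called with an estimated correlation, while PDE340, CS26, PWP2 and NRPC2 were among the clearest increases. In all, 1746 genes rose and 1636 fell, of which 152 and 1034 by at least 2-fold. The increases with a symbol and the smallest p were PDE340 (64.8 ± 5.71 CPM in Col-0, 191 ± 8.25 in asil1-1, 1.56 ± 0.12, adjusted p = 4.57e-08) and the chloroplast cysteine synthase family gene CS26 (1.52 ± 0.12, adjusted p = 4.87e-08). Next by p were the ribosome biogenesis gene PWP2 (1.44 ± 0.11, adjusted p = 4.91e-08) and NRPC2, a large subunit of RNA polymerase III (21.5 ± 3.62 to 66.4 ± 5.37 CPM, 1.62 ± 0.13, adjusted p = 4.91e-08). After ASIL1 itself, the decreases with a symbol and the smallest p were the brassinosteroid biosynthesis gene CPD (-1.09 ± 0.13, adjusted p = 2.05e-05), the methylthioalkylmalate synthase gene MAM3 (IMS2, -1.45 ± 0.18, adjusted p = 2.47e-05) and the auxin response repressor AXR3 (-1.35 ± 0.17, adjusted p = 4.57e-05). XTH12, a cell wall xyloglucan enzyme gene, and the glutathione transferase gene GSTU12 had no count in asil1-1 and were at least 19.6-fold and at least 15-fold lower.

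Of 13 flavonoid and anthocyanin genes tested, 10 fell in asil1-1 and none rose (median log2 fold change -2.18). They included DFR (-4.59 ± 0.67, adjusted p = 0.00031), LDOX (-3.61 ± 0.55, adjusted p = 0.000303), CHS (-3.03 ± 0.47, adjusted p = 0.000968) and F3H (-1.90 ± 0.32, adjusted p = 0.00105). The list was called lower by camera (adjusted p = 1.43e-09, adjusted p = 0.512 with an estimated correlation). All comparisons against Col-0 share the same Col-0 libraries, and the flavonoid and photosynthesis lists were also lower in wild-type Ler. A high level in the Col-0 libraries alone was not tested for the flavonoid and glucosinolate lists in any line, nor for the photosynthesis list in asil1-1, and stays open there. In asil1-1 asil2-1 against asil2-1, which uses no Col-0 library, the flavonoid and glucosinolate lists did not fall. Both were called higher there with the preset correlation, though not with an estimated one. Of 15 glucosinolate genes 10 fell and none rose (adjusted over the list alone, 11 fell and 1 rose, median -0.52, camera adjusted p = 5.73e-06, adjusted p = 0.816 with an estimated correlation). Among them were ESP (-1.05 ± 0.20, adjusted p = 0.00153), BCAT4 (-0.69 ± 0.13, adjusted p = 0.00191) and CYP83A1 (-0.53 ± 0.11, adjusted p = 0.00311). Of 28 nuclear photosynthesis genes 12 fell (18 when adjusted over the list alone) and none rose (median -0.44, camera adjusted p = 1.31e-06, adjusted p = 0.905 with an estimated correlation). LHCB5 (-0.67 ± 0.15, adjusted p = 0.00472), LHCA3 (-0.63 ± 0.14, adjusted p = 0.00521) and LHCA4 (-0.76 ± 0.17, adjusted p = 0.0058) were its clearest members. Of 20 abscisic acid and water deficit genes 7 fell, such as RD22 (-0.90 ± 0.16, adjusted p = 0.000911), ADH1 (-3.58 ± 0.59, adjusted p = 0.00144) and CYP707A1 (-1.60 ± 0.37, adjusted p = 0.00629). The phosphatase gene HAB1 rose (0.51 ± 0.11, adjusted p = 0.00515). This list had a median of -0.47 (camera adjusted p = 0.00132, adjusted p = 0.614 with an estimated correlation).

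Of 18 root markers, 12 fell in asil1-1 and 1 rose (14 and 1 when adjusted over the list alone, median -2.5, camera adjusted p = 7.33e-06, adjusted p = 0.835 with an estimated correlation). EXPA7 of root hairs (-3.65 ± 0.81, adjusted p = 0.005), CASP2 (-2.25 ± 0.50, adjusted p = 0.00515) and MYB36 (-1.92 ± 0.48, adjusted p = 0.0102), both of the endodermis, fell, and SCR rose (0.53 ± 0.11, adjusted p = 0.00254). Genes of iron uptake by the root fell alongside: IRT1 (-4.84 ± 1.16, adjusted p = 0.012), FRO2 (-4.18 ± 1.03, adjusted p = 0.0138) and their regulator FIT (-2.60 ± 0.64, adjusted p = 0.00916). In all, 4 of 13 iron deficiency genes fell and none rose (median -0.66, camera adjusted p = 0.0806). The phosphate transporter gene PHT1-1 also fell (-1.63 ± 0.42, adjusted p = 0.0123), as did the jasmonate-responsive VSP2 (-1.91 ± 0.42, adjusted p = 0.00759). Of 6 shoot meristem markers none changed (median -0.45, camera adjusted p = 0.386). With a root score in the model 393 genes were called in place of 3382, and with Col-0 replicate 3 as the only Col-0 library 202.

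In the libraries labelled asil2-1 against Col-0, all 28 nuclear photosynthesis genes tested fell, and CYP707A3, PUB22, HSF A4A and NAC062 were among the clearest increases. In all, 4298 genes rose and 3783 fell (627 and 1583 by at least 2-fold). CYP707A3, an abscisic acid 8'-hydroxylase gene, rose from 2.89 ± 0.42 to 57 ± 8.88 CPM (4.30 ± 0.26, adjusted p = 1.33e-09). The ubiquitin ligase gene PUB22 (2.26 ± 0.14, adjusted p = 1.33e-09), the heat stress transcription factor gene HSF A4A (2.40 ± 0.15, adjusted p = 1.33e-09) and the NAC factor gene NAC062 (2.08 ± 0.15, adjusted p = 6.57e-09) rose as well. UBC12 and PAB5 had no count in Col-0 and were at least 11.8-fold and at least 7.66-fold higher. The one-helix protein gene OHP fell from 92 ± 11 to 17.5 ± 1.32 CPM (-2.40 ± 0.16, adjusted p = 1.4e-09).

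The photosynthesis list in asil2-1 had a median of -0.98 (camera adjusted p = 1.16e-13, adjusted p = 0.835 with an estimated correlation). Its clearest members were the photosystem genes PSAH1 (-1.99 ± 0.19, adjusted p = 3.27e-07), PSAG (-1.53 ± 0.16, adjusted p = 3.27e-07), PSBR (-1.85 ± 0.20, adjusted p = 8.56e-07) and the Rubisco small subunit gene RBCS3B (-1.64 ± 0.20, adjusted p = 3.33e-06). Many of its members have short transcripts, and the median was -0.80 after correction for the length trend. Counts of near-identical copies, such as the RBCS and LHCB1 genes, are uncertain because the counting of multiply mapping reads is not given in the sources used here. Of 13 flavonoid genes 10 fell (12 when adjusted over the list alone, median -1.70, camera adjusted p = 1.86e-05, adjusted p = 0.828 with an estimated correlation). The clearest were UF3GT (-4.27 ± 0.71, adjusted p = 9.84e-05), 4CL3 (-1.31 ± 0.22, adjusted p = 0.000109) and TT19 (-2.86 ± 0.53, adjusted p = 0.000295). Of 15 glucosinolate genes 11 fell (median -0.73, camera adjusted p = 2.56e-05, adjusted p = 0.835 with an estimated correlation). They included MAM3 (-1.34 ± 0.17, adjusted p = 5.02e-06), ESP (-1.29 ± 0.19, adjusted p = 3.55e-05) and CYP83A1 (-0.73 ± 0.11, adjusted p = 3.63e-05). Of 18 root markers 8 fell and 1 rose (10 and 1 when adjusted over the list alone, median -1.55, camera adjusted p = 0.0339, adjusted p = 0.905 with an estimated correlation).

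Individual hormone and clock genes also rose in asil2-1, in lists that moved both ways. The salicylate pathway genes CBP60G (2.22 ± 0.21, adjusted p = 2.09e-07), SAG101 (1.41 ± 0.14, adjusted p = 2.37e-07) and WRKY46 (2.99 ± 0.36, adjusted p = 2.83e-06) rose. In their list 6 of 23 genes rose and 1 fell (5 and 0 when adjusted over the list alone, median -0.01, camera adjusted p = 0.587). LOX3 (1.8 ± 0.21, adjusted p = 3.82e-06), LOX4 (3.37 ± 0.42, adjusted p = 2.01e-05), MYC2 (1.34 ± 0.19, adjusted p = 3.25e-05) and JAZ1 (1.73 ± 0.32, adjusted p = 0.000489) rose. Of 23 jasmonate and wound genes 6 rose and 3 fell (median 0.12, camera adjusted p = 0.587). Of 14 clock genes 5 rose and 1 fell, with TOC1 (0.87 ± 0.13, adjusted p = 3.25e-05), PRR5 (0.95 ± 0.15, adjusted p = 5.82e-05) and ELF3 (0.72 ± 0.14, adjusted p = 0.00033) higher (median 0.15, camera adjusted p = 0.295). Of 15 chromatin repressors of the embryonic programme 6 rose and none fell (7 and 1 when adjusted over the list alone, median 0.26, camera adjusted p = 0.186). They included the Polycomb genes SWN (0.61 ± 0.10, adjusted p = 9.25e-05) and EMF2 (0.48 ± 0.09, adjusted p = 0.00052) and the remodeller gene PKL (0.49 ± 0.13, adjusted p = 0.00398). After length correction 3 of the 15 rose and 2 fell (median -0.03), and PKL was at -0.03. With both the length correction and a root score, 3156 genes were called in place of 8081, and with Col-0 replicate 3 as the only Col-0 library 3953.

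In asil1-1 asil2-1 against Col-0, 26 of 28 nuclear photosynthesis genes fell and none rose, and GATB, CS26 and PDE340 were the clearest increases by p among genes with a symbol. In all, 4007 genes rose and 3676 fell (507 and 1518 by at least 2-fold). GATB, for an organellar glutamyl-tRNA amidotransferase subunit, rose from 74.4 ± 5.48 to 255 ± 18.7 CPM (1.78 ± 0.09, adjusted p = 4.75e-11). Among genes with a symbol it was followed by CS26 (1.94 ± 0.12, adjusted p = 4.3e-10), PDE340 (1.89 ± 0.12, adjusted p = 8.59e-10), the plastid FtsH gene FTSH12 (1.86 ± 0.13, adjusted p = 1.81e-09) and the helicase gene MAA3 (1.54 ± 0.11, adjusted p = 5.87e-09). PAB5 (at least 14.1-fold higher) and UBC12 (at least 10.8-fold higher) had no count in Col-0. The copper chaperone gene CCH (297 ± 23.3 to 63.8 ± 10.5 CPM, -2.22 ± 0.15, adjusted p = 1.81e-09) and OHP (-2.22 ± 0.16, adjusted p = 3.91e-09) fell. WOX14 and the seed heat stress factor gene HSFA9 had no count in asil1-1 asil2-1 and were at least 20.5-fold and at least 8.92-fold lower.

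The photosynthesis list in asil1-1 asil2-1 had a median of -1.54 (camera adjusted p = 2.26e-17, adjusted p = 0.816 with an estimated correlation). They included PSAG (-1.64 ± 0.16, adjusted p = 2.09e-07), PSAH1 (-1.94 ± 0.19, adjusted p = 5.89e-07), LHCA4 (-1.68 ± 0.18, adjusted p = 6.57e-07) and LHCA2 (-1.51 ± 0.16, adjusted p = 6.57e-07). Of 13 flavonoid genes 8 fell (median -1.25, camera adjusted p = 0.00514, adjusted p = 0.905 with an estimated correlation). They included MYB12 (-2.47 ± 0.47, adjusted p = 0.000344) and F3H (-1.26 ± 0.30, adjusted p = 0.00334). Of 15 glucosinolate genes 7 fell (median -0.33, camera adjusted p = 0.0158, adjusted p = 0.905 with an estimated correlation). They included ESP (-1.19 ± 0.19, adjusted p = 8.81e-05) and MAM3 (-0.97 ± 0.17, adjusted p = 0.00015). Of 18 root markers 8 fell and 1 rose (11 and 1 when adjusted over the list alone, median -1.83, camera adjusted p = 0.0103, adjusted p = 0.905 with an estimated correlation), with PIN2 lower (-2.60 ± 0.59, adjusted p = 0.00209). Of 9 heat shock genes 5 rose and 2 fell (median 0.67, camera adjusted p = 0.346), HSFA2 (2.84 ± 0.59, adjusted p = 0.000786) and HSP101 (0.77 ± 0.17, adjusted p = 0.00107) among those that rose. After length correction HSP101 was at 0.42 and no longer called, and with a root score the flavonoid and glucosinolate lists were not called (camera adjusted p = 0.43 and 0.251). With both the length correction and a root score 3896 genes were called in place of 7683, and with Col-0 replicate 3 as the only Col-0 library 3895.

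The asil1-1 asil2-1 libraries were also compared with those labelled asil1-1 and asil2-1. Against asil1-1, 1217 genes rose and 1848 fell. The increases included CYP707A3 (1.28 ± 0.329 to 23 ± 9.05 CPM, 4.2 ± 0.30, adjusted p = 5.18e-08), the ethylene biosynthesis gene ACS6 (3.20 ± 0.30, adjusted p = 1.79e-06), PUB22 (1.56 ± 0.14, adjusted p = 2.69e-07) and HSF A4A (1.42 ± 0.15, adjusted p = 2.38e-06). OHP (-2.19 ± 0.15, adjusted p = 2.18e-08), the glycine-rich protein gene GRP-3 (2860 ± 513 to 531 ± 94.4 CPM, -2.43 ± 0.19, adjusted p = 1.15e-07) and CCH (-1.67 ± 0.15, adjusted p = 2.69e-07) were lower. The mitochondrial SDH3-1 (-4.17 ± 0.65, adjusted p = 0.000136) and TOM7-2 (-3.29 ± 0.91, adjusted p = 0.0167) were lower too, TOM7-2 no longer called after length correction (-2.36). Of 28 photosynthesis genes 24 fell (26 when adjusted over the list alone, median -0.88, camera adjusted p = 3.7e-17, adjusted p = 0.816 with an estimated correlation). Root markers had a median of 0.54 in this comparison. Of 13 flavonoid genes 3 rose (4 when adjusted over the list alone, median 0.92, camera adjusted p = 0.00683, adjusted p = 0.905 with an estimated correlation). LDOX (2.36 ± 0.57, adjusted p = 0.00728) and DFR (2.88 ± 0.71, adjusted p = 0.00988) were among them. Of 23 salicylate and defence genes 6 rose (median 0.47, camera adjusted p = 0.000276, adjusted p = 0.905 with an estimated correlation). Of 20 abscisic acid genes 4 rose and 1 fell (6 and 1 when adjusted over the list alone, median 0.19, camera adjusted p = 0.0339, adjusted p = 0.835 with an estimated correlation, camera adjusted p = 0.0713 with a root score). Genes that moved with the asil2-1 label in both backgrounds numbered 755 higher (267 by chance) and 1337 lower (356.9 by chance), with 46 in opposite directions. After length correction they numbered 652 higher (164 by chance) and 734 lower (202.7 by chance), with 51 in opposite directions. The chance values take every gene as equally likely to be called, which was not checked.

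Against the libraries labelled asil2-1, 621 genes rose and 595 fell in asil1-1 asil2-1. CS26 (17 ± 1 to 66.4 ± 1.31 CPM, 1.97 ± 0.12, adjusted p = 3.92e-10), GATB (1.18 ± 0.09, adjusted p = 1.86e-08) and the ferritin gene FER2 (3.45 ± 0.37, adjusted p = 3.03e-06) were higher. ASIL1 (-2.33 ± 0.13, adjusted p = 3.58e-10), RRTF1 (-2.82 ± 0.84, adjusted p = 0.0479) and TDR1 (-2.75 ± 0.81, adjusted p = 0.0451) were lower. Of 28 photosynthesis genes 10 fell and 2 rose (14 and 3 when adjusted over the list alone, median -0.39, camera adjusted p = 0.00137, adjusted p = 0.905 with an estimated correlation). None of 13 flavonoid genes passed on its own, while the list was called higher (median 0.78, camera adjusted p = 0.00482, adjusted p = 0.905 with an estimated correlation). Of 15 glucosinolate genes 3 rose (median 0.32, camera adjusted p = 0.00125, adjusted p = 0.905 with an estimated correlation). The clearest was CYP79F1 (0.61 ± 0.14, adjusted p = 0.0106). Of 13 iron deficiency genes 3 rose (7 when adjusted over the list alone, median 1.16, camera adjusted p = 0.0416, adjusted p = 0.905 with an estimated correlation). The clearest was NAS4 (1.16 ± 0.22, adjusted p = 0.00192). The iron list was not called after length correction (camera adjusted p = 0.0546) or with a root score (0.0681). With both the length correction and a root score 2347 genes were called in place of 1216.

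A set of genes moved with the asil1-1 label in 3 comparisons that share no library: asil1-1 against Col-0, asil1-1 asil2-1 against asil2-1, and asil1-1 asil2-2 against Ler. In these, 204 genes were higher in all 3 (8.19 by chance) and 28 were lower in all 3 (6.72 by chance). GATB, CS26, PDE340, PWP2, NRPC2, FTSH12, MAA3 and FER2 were among the higher genes, and CPD, RRTF1, LHCA1, LHCA3, LHCA4 and ASIL1 itself among the lower, of which RRTF1 was not shared after length correction. The corresponding numbers were 230 (9.36 by chance) and 33 (9.79 by chance) after length correction, and 127 (2.54 by chance) and 19 (1.2 by chance) with the length correction and a root score together. All these chance values take every gene as equally likely to be called in each comparison, which was not checked.

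In the libraries labelled asil2-2 against Ler, 8 of 20 abscisic acid and water deficit genes fell and 4 of 23 salicylate and defence genes rose, in lists that were not called with an estimated correlation. In all, 468 genes rose and 699 fell (146 and 193 by at least 2-fold). CYP707A3, which rose in asil2-1, fell here from 13 ± 3.84 to 1.4 ± 0.263 CPM (-3.22 ± 0.27, adjusted p = 5.12e-07). The mitochondrial dicarboxylate carrier gene DIC2 (-3.50 ± 0.59, adjusted p = 0.00297), the cold response regulator CBF1 (-4.21 ± 0.71, adjusted p = 0.00117) and the jasmonate signalling factor MYC3 (-1.17 ± 0.10, adjusted p = 2.24e-07) fell too. The dioxygenase gene 2A6 rose (1.4 ± 0.10, adjusted p = 2.45e-08), and WRKY38, with no count in Ler, was at least 15.7-fold higher.

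Of 20 abscisic acid and water deficit genes 8 fell and none rose in asil2-2 (12 and 1 when adjusted over the list alone, median -0.89, camera adjusted p = 7.32e-08, adjusted p = 0.121 with an estimated correlation). Among them were COR47 (-0.83 ± 0.12, adjusted p = 0.000282), RD26 (-1.46 ± 0.23, adjusted p = 0.000947) and the abscisic acid synthesis gene NCED3 (-2.61 ± 0.40, adjusted p = 0.00107). Of 23 salicylate and defence genes 4 rose: WRKY38 (adjusted p = 0.00841), WRKY54 (2.02 ± 0.46, adjusted p = 0.0155), NIMIN1 (4.35 ± 1.09, adjusted p = 0.0203) and SARD1 (2.08 ± 0.54, adjusted p = 0.03). Their list had a median of 0.89 (camera adjusted p = 0.00472, adjusted p = 0.905 with an estimated correlation). Of 28 photosynthesis genes 5 fell (7 when adjusted over the list alone, median -0.36, camera adjusted p = 1.89e-05, adjusted p = 0.905 with an estimated correlation). Of 13 flavonoid genes 2 rose (median 0.37, camera adjusted p = 0.0466, adjusted p = 0.905 with an estimated correlation). These were UGT75C1 (1.35 ± 0.27, adjusted p = 0.00415) and 4CL3 (1.11 ± 0.23, adjusted p = 0.00624). Of 5 phosphate starvation genes 2 rose (3 when adjusted over the list alone, median 1.14, camera adjusted p = 0.0127, adjusted p = 0.512 with an estimated correlation). These were SPX1 (1.24 ± 0.21, adjusted p = 0.00111) and PHT1-4 (1.14 ± 0.32, adjusted p = 0.0364). None of 5 carbon starvation genes passed on its own, while the list was called lower (median -0.80, camera adjusted p = 0.0416, adjusted p = 0.905 with an estimated correlation). The floral repressor gene FLC rose (1.78 ± 0.41, adjusted p = 0.0116) and SOC1 fell (-0.56 ± 0.10, adjusted p = 0.00178). None of the 18 root markers changed (median -0.17). The number of genes called was 1979 with a root score in place of 1167, and 482 without asil2-2 replicate 2.

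The labels give asil1-1 asil2-2 a mixed background of both ecotypes, and its libraries differed from both wild types. Against Col-0, 3272 genes rose and 3031 fell (784 and 1087 by at least 2-fold); against Ler, 2898 rose and 2648 fell (1308 and 524). The receptor kinase gene CRK4 had no count in Ler and was at least 158-fold higher in asil1-1 asil2-2, and DAR4 was 30.1 ± 7.64 CPM against 0.29 ± 0.155 in Ler (6.96 ± 0.27, adjusted p = 2.72e-14). Both also separate the wild types, Ler being at least 152-fold lower than Col-0 in CRK4 and lower in DAR4 (-7.51 ± 0.26, adjusted p = 3.92e-15). MAM3 was 146 ± 4.42 CPM against 16.6 ± 2.78 in Col-0 (3.14 ± 0.16, adjusted p = 3.94e-12), and the phosphate transporter gene PHT1;2, with no count in Col-0, was at least 14.3-fold higher. FOLT1 rose against Col-0 as well (8.70 ± 1.59 to 41.2 ± 2.74 CPM, 2.23 ± 0.13, adjusted p = 8e-11).

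Genes changed in asil1-1 asil2-2 in the same direction against both wild types numbered 1274 higher and 800 lower (367 and 148 by at least 2-fold). With the smaller of the 2 fold changes given, CYP82C2 (6.93 ± 0.73, adjusted p = 3.7e-06) and GATB (1.27 ± 0.09, adjusted p = 4.79e-10) were higher. The cold-regulated KIN1 (-4.88 ± 0.77, adjusted p = 5.46e-05), CBF1 (-4.66 ± 1.16, adjusted p = 0.00402), SYP31 (-2.59 ± 0.28, adjusted p = 3.89e-07), EMB2654 (-1.4 ± 0.11, adjusted p = 3.98e-09) and COR413-PM1 (-1.14 ± 0.12, adjusted p = 4.92e-07) were lower. Of 20 abscisic acid and water deficit genes 10 fell and none rose against Col-0 (median -0.79, camera adjusted p = 2.87e-05, adjusted p = 0.418 with an estimated correlation). Against Ler 16 fell and none rose (17 and 1 when adjusted over the list alone, median -1.33, camera adjusted p = 7.86e-09, adjusted p = 0.121 with an estimated correlation). KIN2 (-3.81 ± 0.39, adjusted p = 2.91e-06) and COR15A (-3.16 ± 0.48, adjusted p = 6.18e-05) fell against Col-0, and COR47 (-1.46 ± 0.12, adjusted p = 9.43e-09) and NCED3 (-3.49 ± 0.44, adjusted p = 1.57e-05) against Ler. Of 23 salicylate and defence genes 11 rose and none fell against Col-0 (12 when adjusted over the list alone, median 1.2, camera adjusted p = 0.00089, adjusted p = 0.905 with an estimated correlation). Against Ler 14 rose and none fell (median 1.27, camera adjusted p = 2.83e-05, adjusted p = 0.905 with an estimated correlation). FRK1 was higher against Col-0 (1.69 ± 0.37, adjusted p = 0.00145) and against Ler (2.16 ± 0.37, adjusted p = 0.000159). Without asil1-1 asil2-2 replicate 3, 1351 genes passed against both wild types in place of 2074.

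Of 28 photosynthesis genes 26 fell in asil1-1 asil2-2 against Col-0 (median -1.19, camera adjusted p = 3.7e-17, adjusted p = 0.816 with an estimated correlation). Against Ler 20 fell (median -0.52, camera adjusted p = 2.53e-07, adjusted p = 0.905 with an estimated correlation), where PSAF fell (-1.12 ± 0.14, adjusted p = 3.51e-06). Of 13 iron deficiency genes 8 rose and 1 fell against Ler (9 and 1 when adjusted over the list alone, median 1.35, camera adjusted p = 0.0128, adjusted p = 0.905 with an estimated correlation). They included NAS4 (1.21 ± 0.20, adjusted p = 0.000124), BHLH100 (3.69 ± 0.89, adjusted p = 0.00549) and BHLH38 (2.51 ± 0.74, adjusted p = 0.017). Of 18 root markers 1 rose and 2 fell against Col-0 (median -0.58), and 2 rose and 1 fell against Ler (median 0.25). Of 13 fatty acid and oil synthesis genes 5 fell against Ler and none rose (median -0.27, camera adjusted p = 0.0806). The clearest was MOD1 (-0.57 ± 0.11, adjusted p = 0.000349). Of 10 SIP1-clade trihelix genes, which include ASIL1 and ASIL2, 5 rose and 2 fell against Ler (median 0.30, camera adjusted p = 0.508), AT3G58630 rising (0.75 ± 0.14, adjusted p = 0.000431).

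**Figure D4:**
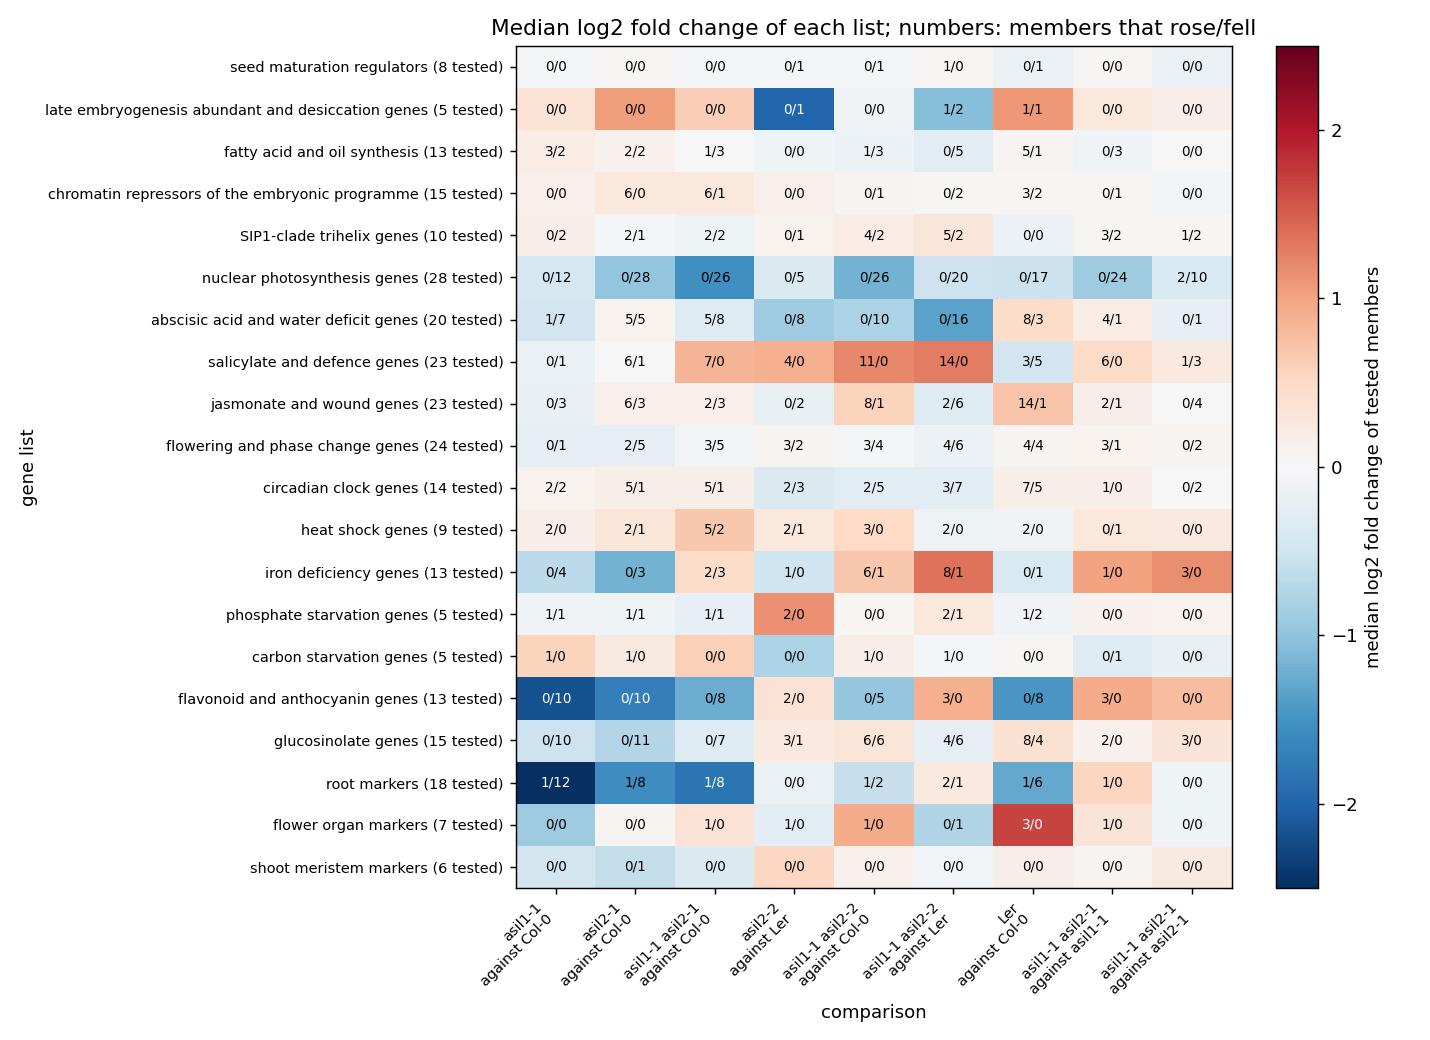
Median log2 fold change of the members tested of each gene list in each comparison of 2 groups.

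Genes shared by the 2 groups with both labels were compared in contrasts with no library in common, asil1-1 asil2-1 against Col-0 and asil1-1 asil2-2 against Ler. Shared genes numbered 839 higher (592.8 by chance, ratio 1.42, Fisher exact p = 1.98e-32) and 568 lower (496.9 by chance, ratio 1.14, Fisher exact p = 0.000178). A further 1008 genes were called in opposite directions, and the correlation of the fold changes across all genes was -0.05 (rank correlation 0.06). The ratios were 1.84 and 1.28 at an adjusted p under 0.01, 1.61 and 1.24 after length correction, and 3.6 (122 genes, 33.9 by chance) and 2.14 (87 genes, 40.6 by chance) for genes with an absolute log2 fold change of at least 1, where 267 genes went in opposite directions. The opposite genes pool both combinations of directions, so their number cannot be set against the shared genes of either direction alone. No chance value was computed for opposite genes, so the ratios alone do not show that the 2 groups responded alike. Gene-by-gene Fisher p values treat genes as independent, which correlated genes are not.

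ASIL factors are known as repressors of seed maturation genes, and that programme was measured in these 14-day seedlings. LEC1, LEC2, FUS3 and ABI3 had too few counts to be tested. None of the 8 seed maturation regulators that were tested changed in asil1-1, asil2-1 or asil1-1 asil2-1 against Col-0 (medians -0.03, 0.02 and -0.03, camera adjusted p = 0.864, 0.92 and 0.864). AGL15 was -0.64 ± 0.42 (adjusted p = 0.312) and ABI5 0.50 ± 0.38 (adjusted p = 0.383) in asil1-1. None of 5 late embryogenesis abundant genes changed in these lines (medians 0.35, 1.04 and 0.61, camera adjusted p = 0.867, 0.849 and 0.685). Of the 2 seed storage genes with enough counts, PAP85 rose in asil2-1 (2.49 ± 0.77, adjusted p = 0.0168) and was 1.41 ± 0.80 in asil1-1 (adjusted p = 0.247) and 1.97 ± 0.77 in asil1-1 asil2-1 (adjusted p = 0.0544). AT4G36700 passed in asil1-1 asil2-1 (3.20 ± 1.18, adjusted p = 0.0393), but by replicate 2 alone, without which it was at -0.46. It rose in asil1-1 asil2-2 against Col-0 (4.06 ± 1.14, adjusted p = 0.0107) and Ler (3.05 ± 0.95, adjusted p = 0.0222). Of the 2 oil body genes, OLEO4 fell in asil1-1 asil2-1 (-1.41 ± 0.40, adjusted p = 0.00788) and AT3G01570 fell in asil1-1 asil2-2 against Col-0 (-1.78 ± 0.54, adjusted p = 0.0153), at -1.30 and no longer called after length correction.

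The wild types differed in 7077 genes, 3501 higher and 3576 lower in Ler than in Col-0 (648 and 1735 by at least 2-fold). The glucosinolate genes ESP (24.6 ± 1.64 CPM in Col-0, 1780 ± 76.7 in Ler, 6.18 ± 0.21, adjusted p = 4.3e-15), AOP3 (7.58 ± 0.34, adjusted p = 7.37e-12) and MAM3 (2.56 ± 0.16, adjusted p = 2.68e-11) were higher in Ler, and ESM1 was lower (-2.88 ± 0.14, adjusted p = 6.71e-13). Of 15 list members 8 were higher and 4 lower (median 0.38, camera adjusted p = 0.312). Of 23 jasmonate and wound genes 14 were higher and 1 lower (15 and 1 when adjusted over the list alone, median 0.71, camera adjusted p = 0.00655, adjusted p = 0.905 with an estimated correlation). They included LOX2 (1.68 ± 0.23, adjusted p = 1.97e-05), MYC2 (1.33 ± 0.19, adjusted p = 2.76e-05) and AOS (0.96 ± 0.16, adjusted p = 5.68e-05). Of 13 flavonoid genes 8 were lower (11 when adjusted over the list alone, median -1.46, camera adjusted p = 0.000608, adjusted p = 0.873 with an estimated correlation). They included 4CL3 (-2.07 ± 0.24, adjusted p = 6.63e-07), and of 28 photosynthesis genes 17 were lower (18 when adjusted over the list alone, median -0.54, camera adjusted p = 0.000102, adjusted p = 0.905 with an estimated correlation). Of 24 flowering genes 4 were higher and 4 lower (median 0.07, camera adjusted p = 0.904), SOC1 rising (1.16 ± 0.10, adjusted p = 1.74e-08) and FLC falling (-2.16 ± 0.42, adjusted p = 0.000425). Of 7 flower organ markers 3 were higher (6 when adjusted over the list alone, median 1.68, camera adjusted p = 0.0554), and of 18 root markers 6 were lower and 1 higher (median -1.27, camera adjusted p = 0.229). With Col-0 replicate 3 as the only Col-0 library 3762 genes were called.

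Levels of the ecotype-dependent genes along the chromosomes of asil1-1 asil2-2 were placed on a scale from 0 (Col-0) to 1 (Ler). Of 2365 genes 52.3% lay nearer to Col-0, as did 84 of 156 windows of 15 genes. Without asil1-1 asil2-2 replicate 2 these were 49.5% and 73 of 158, after length correction 57.6% and 93 of 142, and for genes with an absolute log2 fold change of at least 2 between the wild types 61% and 40 of 57, so that no side is favoured in every setting. Of the 156 windows 106 had a median between 0.25 and 0.75. Such a median can mix genes near either wild type, as in a window of chromosome 2 with a median of 0.52 and quartiles of 0 and 0.89. The index was not computed with a root score or with Col-0 replicate 3 as the only Col-0 library. Chromosome 1 was nearest to Col-0 (66.7% of genes and 34 of 41 windows), against 39.5% of genes on chromosome 2, 45.8% on chromosome 3, 53.2% on chromosome 4 and 48.9% on chromosome 5. Within 1 Mb of ASIL1 the median over 56 genes was 0.3 (quartiles 0.04 and 0.73), no nearer to Col-0 than chromosome 1 as a whole (median 0.27). Within 1 Mb of ASIL2 the median over 47 genes was 0.75 (quartiles 0.27 and 1.13), against 0.57 for chromosome 3 as a whole. The near neighbour of ASIL1, ESP, was at the Col-0 side (11 ± 1.04 CPM against 1780 ± 76.7 in Ler), and the near neighbour of ASIL2, ESM1, at the Ler side (22.7 ± 1.43 CPM against 316 ± 24.5 in Col-0).

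**Figure D5:**
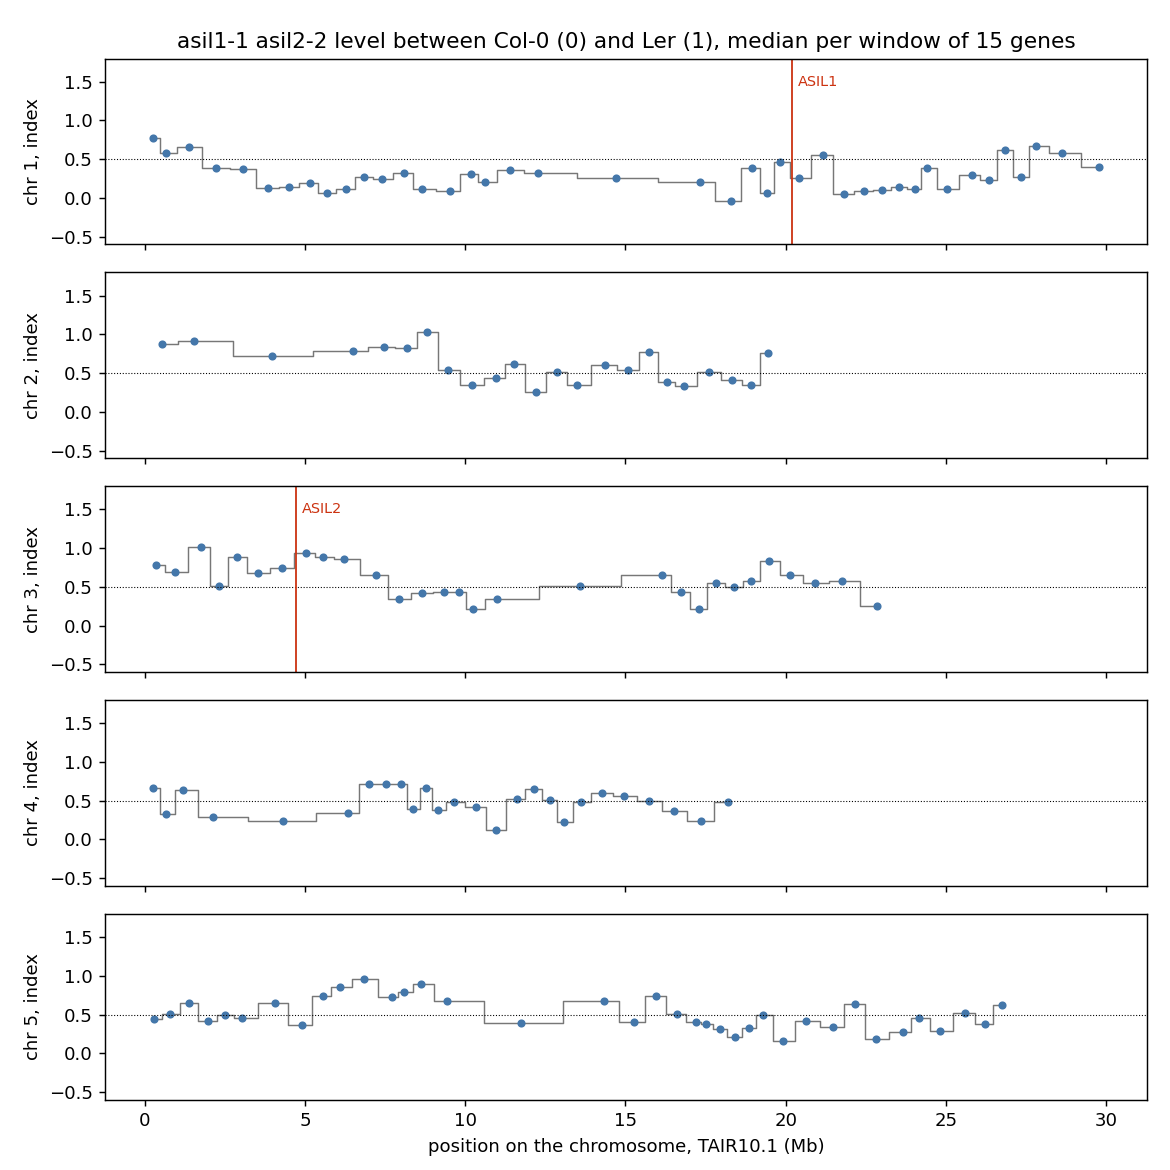
Position of asil1-1 asil2-2 between Col-0 (0) and Ler (1) along the 5 chromosomes, as the median of windows of 15 ecotype-dependent genes, with ASIL1 and ASIL2 marked.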

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

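The tests of the 3 patterns below were all chosen only after the result was seen. The bounds for the photosynthesis genes were also written after their values were known. Those for the root markers and the rapid stress genes were written before the tested values were known, except for ASIL2 in asil2-2, but after similar stress genes had been looked at in the same comparisons. For 4 tests of these last patterns and for asil2-1 against asil1-1 in the photosynthesis genes a bound first written was met, but the test is read as undecided for the reason given beside it. The test of the difference between effects and the splits of the libraries were fixed before the data were examined.

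The effect of the libraries labelled asil2-2 (against Ler) differed from that of asil2-1 (against Col-0) in 4437 genes by the test of the difference itself. With length correction and a root score together 2975 genes were called. Allele and ecotype are confounded in this difference, so it cannot be assigned to the asil2 alleles. Genes with such a difference included PCC1 (7.96 ± 1.32), CYP707A3 (-7.52 ± 0.38), ASIL2 (-3.90 ± 0.28), WRKY11 (-3.26 ± 0.22), PUB22 (-3.14 ± 0.19), OHP (2.81 ± 0.22) and 2A6 (1.61 ± 0.14). Among 100 splits of the same libraries only the real one, counted as 1, reached 4437, and the highest other reached 3422. These splits mix ecotypes whose wild types differ in 7077 genes, so they cannot part chance from ecotype, and chance is not excluded. In asil1-1 asil2-1 the departure from the sum of the asil1-1 and asil2-1 effects passed its test in 892 genes, such as CHIL (2.66 ± 0.38), MAM3 (IMS2, 1.83 ± 0.25), TLL1 (1.71 ± 0.23), ASIL2 (-1.88 ± 0.27), ABCG5 (-1.31 ± 0.19) and BGLU44 (-0.93 ± 0.13). Here 8 of 100 splits, the real one included, gave at least as many genes, the highest other giving 4771, several times the real count, which points to a structure of the samples. The 4 genotypes themselves are such a structure, since these splits mix them, and chance is not excluded. No explanation was tested for the departure, and with Col-0 replicate 3 as the only Col-0 library it was called for 0 genes by edgeR (2484 at an unadjusted p under 0.05) and for 87 by DESeq2.

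Nuclear photosynthesis genes were lower in asil2-1 and asil1-1 asil2-1 than in Col-0. A transcript length trend alone predicts that length correction removes the fall, but the median in asil2-1 stayed at -0.80. More root in the mutant samples predicts higher root markers, and their median in asil2-1 against Col-0 was -1.55. A high level in the Col-0 libraries alone predicts no fall between mutants, yet the length-corrected median of asil1-1 asil2-1 against asil1-1 was -0.81. In that comparison, however, the root markers had a median of 0.54, so more root is not excluded there. For asil2-1 the mean list score was lower than that of asil1-1 by 0.59 (difference -0.59, n = 3 each, no overlap), but only -0.42 ± 0.19 after length correction, whose error covers the bound of -0.3. For the falls against Col-0 the length trend and more root are thus too small or of the wrong sign. A high Col-0 level does not account for all of the fall in asil1-1 asil2-1, unless more root lowered the list against asil1-1. It stays open for a part of that fall. The Col-0 libraries had list scores of 0.82, 0.65 and 0.98, and the highest other library, asil1-1 replicate 1, had 0.56. For asil2-1 a high Col-0 level stays open, and for both lines a genotype effect or another difference in growth between the groups of seedlings. Batches are not given in the labels, and no later collection of the same lines is available here.

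Root markers were lower in asil1-1, asil2-1 and asil1-1 asil2-1 than in Col-0. If Col-0 replicates 1 and 2 alone set the difference, fewer than 4 markers should fall against Col-0 replicate 3. In asil1-1 0 of 18 did by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2, and by edgeR 0 did in asil2-1 and in asil1-1 asil2-1, 0 at an unadjusted p under 0.05. The medians were -0.97 (from -2.5), -0.28 (from -1.55) and -0.46 (from -1.83), asil2-1 replicates 2 and 3 and asil1-1 asil2-1 replicate 1 scoring at least as high as Col-0 replicate 3. However, had the fold changes with all libraries held, the errors with a lone Col-0 library (medians 1.13, 1.03 and 1.02) would have let 0, 0 and 1 of the markers be called, so the counts of calls decide nothing. At an unadjusted p under 0.05 it would have been 10, 5 and 6, so the falls against this library were smaller, which a choice of the Col-0 library with the lowest score also gives. A smaller share of root should lower all root cell types alike, within a bound of 1, and the medians of 4 root hair genes (-3.21) and 6 endodermis genes (-2.08) differed by 1.13 (exact permutation p = 0.0143 over 210 assignments of genes). That p treats correlated genes as independent and tests for any difference, not for one past the bound. By scores per library the difference was -1.37 with a standard error of 0.5, too wide to pass the bound, so a smaller share of root is not excluded. A high root content of 2 of the Col-0 libraries, a smaller share of root in the mutants and an effect of genotype on roots all stay open.

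Of 11 rapid stress genes (TCH2, TCH3, TCH4, CML37, CML38, WRKY33, ZAT12, ERF104, BAP1, SZF2 and MPK3, chosen after the first values were seen and none of them among the genes named before), all rose in asil2-1 and 7 in asil1-1 asil2-1, and 6 fell in asil2-2. A general rapid response of the collected seedlings, such as to handling, predicts that this list also moves in asil2-2, and its median there was -1.45. An effect of genotype predicts the same, and similar genes had been seen to move there before, so this decides nothing. The raised ASIL2 transcript predicts a higher list wherever ASIL2 is raised, but in asil1-1 asil2-2 the lower of the 2 medians was -0.56 (against Ler; 0.41 against Col-0). That line has a mixed background and its list score (-0.36 ± 0.14) lies between those of Col-0 (-0.51 ± 0.61) and Ler (0.20 ± 0.24), so that this excludes nothing. From asil2-1 to asil1-1 asil2-1 both ASIL2 (-1.37 ± 0.19) and the list (median -1.1, 6 of 11 lower) fell, as the raised transcript would predict. In asil2-2 ASIL2 was not raised (-0.38 ± 0.20 against Ler). A raised transcript predicts a higher list, so it could not account for the fall there at any ASIL2 level, and that fall does not test it. Whether the list follows a lower ASIL2 level was not tested. A response of the seedlings at collection and another effect of genotype stay open for the whole pattern, and the raised ASIL2 transcript for asil2-1 and asil1-1 asil2-1 alone.

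In the 9 comparisons of 2 groups, 10 splits of the 6 libraries exist, so that no share under 0.05 can arise, and the real split, counted as 1, gave the most calls in each. The highest other split gave 0 genes in Ler, asil1-1 asil2-2, asil1-1 and asil2-1 against Col-0, 38 in asil1-1 asil2-1 against Col-0, 3 in asil2-2 against Ler, 308 in asil1-1 asil2-2 against Ler, and 1 in asil1-1 asil2-1 against asil1-1 and against asil2-1. For genes changed in asil1-1 asil2-2 against both wild types, 6 of 100 splits gave at least as many as the real 2074, the highest other giving 2833. These splits mix wild types that differ in 7077 genes, so they cannot part chance from ecotype, and chance is not excluded.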

How the results depend on the processing

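Counts of genes called stayed within 1.5 times under RLE scaling, both other filters, removal of organellar genes, a fit of the compared groups alone, length correction and a replicate block. The genes called were less stable than their counts under length correction. Calls kept in the same direction were 4162 of 8081 in asil2-1 and 4605 of 7683 in asil1-1 asil2-1, each against Col-0. They were 1983 of 3065 in asil1-1 asil2-1 against asil1-1, but 5458 of 5546 in asil1-1 asil2-2 against Ler. The replicate block, with 3419 calls in asil1-1 in place of 3382, rests on shared numbers only, since samples with the same number were not more alike (correlations from -0.4 to 0.35). Lone samples left by a fit are assumed to vary like the other groups.

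With Col-0 replicate 3 as the only Col-0 library, chosen after seeing the data, calls against Col-0 were 202 in asil1-1 (3382 with all), 3953 in asil2-1 (8081), 3895 in asil1-1 asil2-1 (7683), 3942 in asil1-1 asil2-2 (6303) and 3762 in Ler (7077), 2020 for the difference of the asil2 effects (4437) and 0 for the non-additivity (892); fewer samples lower power. With a root score, also chosen after seeing the data and itself different between the groups, calls were 393 in asil1-1, 1979 in asil2-2 against Ler (1167) and 44 for the non-additivity. With length correction and root score together they were 373 in asil1-1, 3156 in asil2-1, 3896 in asil1-1 asil2-1, 2169 in asil2-2, 2347 in asil1-1 asil2-1 against asil2-1 (1216) and 42 for the non-additivity. DESeq2 called 1513 genes for the non-additivity. The cause of these shifts was not tested.

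Leaving out 1 library at a time gave 1515 (without Col-0 replicate 2) to 3907 (without Col-0 replicate 3) in asil1-1, with 1745 without Col-0 replicate 1, 1988 without asil1-1 replicate 2 and 1562 without asil1-1 replicate 3. In asil2-2 it gave 482 (without asil2-2 replicate 2) to 1371 (without asil2-2 replicate 3), with 723 without asil2-2 replicate 1, 516 without Ler replicate 2 and 565 without Ler replicate 3. Against both wild types asil1-1 asil2-2 gave 1351 (without its replicate 3) to 2426. For asil1-1 asil2-1 the range was 2001 (without its replicate 3) to 2499 against asil1-1, and 649 (without its replicate 1) to 1063 against asil2-1, with 797 without its replicate 3, 717 without asil2-1 replicate 2 and 698 without asil2-1 replicate 3. The non-additivity ranged from 196 (without asil1-1 asil2-1 replicate 1) to 1838 (without Col-0 replicate 3). It was 246 and 236 without Col-0 replicates 1 and 2, 1414 and 502 without asil1-1 asil2-1 replicates 2 and 3, 338 and 229 without asil1-1 replicates 2 and 3, and 331 and 508 without asil2-1 replicates 1 and 3. All other counts stayed within 1.5 times.

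Of 214 values of named genes, 2 that passed the threshold changed sign: PKL in asil2-1 was at -0.03 after length correction, and AT4G36700 in asil1-1 asil2-1 ranged from -0.46 (without replicate 2 of that line) to 4.23 (without Col-0 replicate 1). Sign changes of values that did not pass were not counted. All 214 kept their side of the threshold under RLE scaling and without organellar genes, 208 under length correction, 185 with a root score and 180 with both. With Col-0 replicate 3 as the only Col-0 library 95 of 142 did and 47 were weaker, and of 1374 values with 1 library left out 1309 did and 62 were weaker.

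Of 180 camera tests 37 were called with the preset correlation and 0 with an estimated correlation, while fry called 37, of which 24 were among the 37 of the preset correlation. RLE scaling, the replicate block and length correction each kept 36 of the 37, and a root score kept 30. The shallowest library, Ler replicate 1 at 6.52 M counts, holds 3 counts at 0.46 CPM, so that weaker genes there are not resolved.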

Other observations

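The test of a promoter element below was chosen only after the shared genes had been seen.

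Some single genes moved in ways the comparisons above did not describe. In asil1-1 asil2-2 the squamosa-type flowering genes SPL3 (-1.24 ± 0.19 against Col-0, adjusted p = 5.06e-05, and -1.28 ± 0.19 against Ler, adjusted p = 2.71e-05) and SPL9 (-1.11 ± 0.27, adjusted p = 0.00363, and -1.44 ± 0.26, adjusted p = 0.000292) fell against both wild types, within a flowering list of 24 in which 3 rose and 4 fell against Col-0 and 4 rose and 6 fell against Ler. SPL3 also fell in asil1-1 asil2-1 (-1.47 ± 0.20, adjusted p = 9.39e-06) and in asil2-1 (-0.81 ± 0.19, adjusted p = 0.00197), where it was at -0.36 and no longer called after length correction. The gene PRR5 of the clock fell in asil2-2 (-1.15 ± 0.15, adjusted p = 8.86e-05) and in asil1-1 asil2-2 against Ler (-1.21 ± 0.15, adjusted p = 3.64e-06), where GI also fell (-1.08 ± 0.16, adjusted p = 3.74e-05) and LHY rose (1.06 ± 0.23, adjusted p = 0.00224). The clock list of 14 was not called in either comparison: 2 rose and 3 fell in asil2-2 (3 and 6 when adjusted over the list alone, median -0.36, camera adjusted p = 0.108, 0.0454 after length correction), and 3 rose and 7 fell in asil1-1 asil2-2 against Ler (median -0.28, camera adjusted p = 0.107). Collection times are not given in the sources used here.

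One hypothesis was tested on the genes that rose with the asil1-1 label in the 3 comparisons that share no library and also in asil1-1 asil2-2 against Col-0 (187 with the promoter sequence read). If ASIL1 repressed them by a GT element, the element GTGATT within 500 nt upstream should be more frequent than in other tested genes. It was found in 25.1% of them and in 30% of 19297 others (odds ratio 0.78, 95% interval 0.55 to 1.1, Fisher exact p = 0.172), and a control sequence, GTTAGT, in 33 of the 187 and in 21% of the others. The hypothesis was not borne out by this test, which covers 1 short element and does not exclude others.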
